A study of Mus musculus with 8 samples.

How the data were processed

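Fibro/adipogenic progenitors (FAPs), the PDGFRα-positive stromal cells of skeletal muscle, were sorted from hindlimb muscles of 8-month-old female mice, either wild type C57BL/6 or dysferlin-deficient. Per the labels' protocols, muscle was digested with collagenases and dispase, live PDGFRα-positive single cells were collected by flow cytometry, and libraries were made with the droplet-based 10x Genomics 3′ kit, version 3. The labels give the strain of the knockout animals in a form that differs from the protocol text, so it is called the dysferlin knockout throughout. The labels list 4 samples in each group. The deposited files hold 1 matrix of unique molecular identifier (UMI) counts per group, all barcodes of a matrix carry the same suffix, no barcode is repeated, and nothing maps cells to samples. Each group was therefore treated as 1 library.

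The values are raw UMI counts per gene and barcode, as deposited by the authors. Cell Ranger 3.0.0, Seurat and the mm10 build are named in the submitters' processing notes, with no role given for Seurat. The matrices carry software version 3.0.2, per the file headers. The rule that separated cells from empty droplets is not given in the sources used here. The lowest total was 501 UMIs per barcode in the wild type matrix and 500 in the knockout matrix.

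Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library through scanpy 1.11.5, called 4 wild type and 6 knockout doublets, which were removed. The sort had already gated out doublets by pulse width, per the labels' protocols. The remaining cells of both libraries were clustered together with no integration: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and Leiden clustering ran at resolution 0.8 on 15 neighbours. A cluster was a FAP candidate where at least 6 of 10 fixed FAP markers were seen in at least 50% of its cells, fewer than 2 markers of any other of the 16 fixed classes were at least 2-fold above the rest in at least 25% of its cells, and its median relative depth was not below a 1 to 3 ratio of its library's. All other cells were clustered again (resolution 1, 15 components) and named for another class where at least 3 of its markers were found and no other class came near. A cluster with at least 6 FAP markers in at least 50% of its cells could not be named for another class. For this naming the lymphatic endothelial markers were joined to the endothelial ones as 1 class. A FAP candidate was accepted where its 10 leading genes over the cells of the other named classes held no more markers of another class than of its own. Every candidate passed. The other named classes were endothelial-like, macrophage- or monocyte-like and T- or NK-cell-like, few cells in all. This check is therefore weak between FAPs and other stromal cells, such as tenocyte- or mural-type cells.

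The markers were fixed before the data were examined, but this naming rule was settled afterwards. An earlier form judged the 10 leading genes over all other cells, which are mostly FAPs too, and left out clusters 0 and 6. Those clusters hold 17.1% of the wild type cells and 8.62% of the knockout cells, and the results without them are given as an alternative. Clusters that carry at least 6 FAP markers but stayed unnamed hold 6.25% of the wild type cells and 4.94% of the knockout cells.

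UMIs were summed per gene over the FAP-like cells of each library and divided by the library's FAP-like total to give CPM, the number of UMIs in every 1000000. The log2 ratio of knockout over wild type has an exact conditional binomial 95% interval, UMI sums have exact Poisson 95% intervals, and shares of cells have exact Clopper-Pearson 95% intervals. All these intervals and limits cover counting error only: with 1 library per group there is no replicate check, no test between groups and no p-value, and group, strain and library preparation cannot be told apart. Genes with a mean CPM of at least 20 over both libraries were described, and a difference of at least 2-fold was the size criterion. A count of 0 was taken to allow up to 3 counts, or 0.209 CPM in the wild type and 0.161 CPM in the knockout FAP-like cells. On counts simulated as Poisson draws with the totals of the whole matrices, genes made 4-fold higher came out with a median estimate of 3.99-fold. Intervals covered the true value for 96.0% of unchanged genes and for 90.0% of genes made 2-fold lower. A list of unchanged genes stood at percentile 94.7. The simulation checks the calculation and not the spread between cells or animals.

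Different clusters hold most FAP-like cells in the 2 libraries, so ratios were also computed within each of the 9 FAP-like clusters that have at least 25 cells of each library (1527 wild type and 709 knockout cells), for genes with at least 10 UMIs in the cluster. The median over these shared clusters is given beside the class-level value of each list and of part of the named genes. Because clusters are built from the same genes, it can understate a difference that itself moves cells between clusters.

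For 39 gene lists, the median log2 ratio of the members with a mean CPM of at least 10 was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. Its percentile describes these libraries and is no test. Members at least 1.5-fold higher or lower were counted. Shares of cells with a UMI were compared after each cell was thinned to 2800 UMIs, which left out 152 wild type and 90 knockout FAP-like cells. The background is the share in the endothelial-like cells of both libraries, thinned in the same way.

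The genes named are Dysf; the 12 higher and 12 lower genes whose interval bound nearest to 0 was the largest in size (leaving out mitochondrially encoded genes, Xist, predicted genes, and the erythroid and immunoglobulin families); up to 4 members of each list, by the same measure in either direction; and 24 genes fixed in advance. The samples, lists, markers, this rule and most alternatives were fixed before the data were examined. Alternatives covered the cell filter, doublets, clustering, the definition of FAP-like cells, library scaling (TMM from edgeR 4.0.16 and size factors from DESeq2 1.42.0, used for scaling alone), equal weight per cell, thinning and the expression minimum. Gene positions are from GENCODE release M21 on the same build as mm10, in which 31011 of the 31053 gene identifiers were found. Named genes whose last 500 transcript bases share a 60-base run with another gene are called uncertain where that gene is a close copy. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.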

Results

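Single-cell transcriptomes were collected from PDGFRα-sorted FAPs of hindlimb muscle, to compare these progenitors between wild type mice and mice without dysferlin. Dysferlin is a membrane repair protein, and its loss causes a muscular dystrophy with fatty replacement of muscle. Each group has 4 labelled samples of 8-month-old females, deposited as 1 pooled matrix per group. The wild type matrix held 2073 barcodes with 17642513 UMIs and a median of 8063 UMIs and 2625 genes per barcode. The knockout matrix held 1724 barcodes with 21476948 UMIs and medians of 11734 UMIs and 3416.5 genes. The protocol aimed at about 8000 cells. The quality filter and doublet removal left 1793 wild type and 1578 knockout cells. Every value below compares these 2 libraries, with no replicates.

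Dysferlin itself was barely detected. Dysf (ENSMUSG00000033788, chromosome 6, 84008590 to 84211060 on mm10) had 23 UMIs in the filtered wild type cells (95% Poisson interval 14.6 to 34.5) and 15 in the filtered knockout cells (8.40 to 24.7). The ratio of their CPM was 0.514, with an interval of 0.249 to 1.03. In FAP-like cells alone the sums were 8 and 13 UMIs, or 0.558 and 0.696 CPM, with a ratio of 1.25 (0.479 to 3.47). Both intervals include 1, and 3′ tags do not show whether the transcript is disrupted upstream, so the FAP-like cells give the labels no check from this gene. Outside the FAP-like class the sums were 15 wild type and 2 knockout UMIs, a ratio of 0.148 (0.0165 to 0.638) that runs with the labels but also carries the different makeup of those cells.

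Nearly all cells in both libraries were FAP-like, as the PDGFRα sort sets. FAP-like cells made up 89.4% of the wild type cells (1603 of 1793; 87.9 to 90.8) and 93.2% of the knockout cells (1471 of 1578; 91.9 to 94.4). These shares depended on the clustering and the filter, and with no filter beyond the deposited barcodes the wild type share, 82.9%, was above the knockout share of 81.1%. Endothelial-like cells were 2.23% of the wild type cells (1.60 to 3.03) and 0.380% of the knockout cells (0.140 to 0.826), and macrophage- or monocyte-like cells were 5 in each library. The endothelial-like class joined cluster s4 (28 wild type and 0 knockout cells) and cluster s5 (12 and 6). Cluster s5 had the lymphatic markers Mmrn1, Lyve1 and Prox1 among its leading genes. T- or NK-cell-like cells numbered 7 in the wild type and 1 in the knockout library. The median depth of FAP-like cells was 8644 UMIs in the wild type and 12164 UMIs in the knockout library.

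The FAP-like cells of the 2 libraries fell mostly into different clusters. Cluster 1, led by Cpxm1, C1qtnf3, Mmp3 and Sfrp1, held 38.9% of the knockout FAP-like cells, and cluster 17, led by the immune genes Cxcl9, Ccl2, Ccl7 and Isg15, held 9.38%. These 2 clusters had 8 and 4 wild type cells. Most wild type FAP-like cells were in cluster 4 (15.7%), led by the stress-responsive immediate early genes Egr1, Btg2, Ier2 and Junb, in clusters 5 (15.5%) and 6 (15.4%), and in clusters 11 (11.5%) and 2 (11.1%). A cluster held almost entirely by 1 library can stand for that library and not for a cell state. The 9 shared clusters were led by Cthrc1 and Postn (cluster 0), Hsd11b1 and Nmb (2), Smpd3, Ugdh and Pi16 (3), Egr1 (4), Stmn4 and Inmt (5), Comp and Clu (6), Sema3c and Cd55 (7), Gdf10 and Fmo2 (10), and Apoe and Fst (11).

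The knockout FAP-like cells had more transcripts of most interferon-induced and class I MHC genes measured and of some chemokine, complement and collagen genes, and fewer transcripts of most immediate early genes and of Tsc22d3, Zbtb16, Cdkn1a and Ddit4. Most genes were alike: of 5942 genes with a mean CPM of at least 20, 91.4% lay within 1.5-fold. At least 2-fold higher in the knockout library were 107 genes, and 58 were at least 2-fold lower. The median log2 ratio of all these genes was 0.05. Of the 107, 47 were higher in each of the 9 shared clusters, and of the 58, 32 were lower in each. Over the cells of the shared clusters alone, an alternative chosen after seeing the data, 53 genes were at least 2-fold higher and 31 at least 2-fold lower, 46 and 24 of them shared with the class-level sets. Of the 102 genes named by rule that were at least 1.5-fold apart over the class and measured in shared clusters, 57 were still at least 1.5-fold apart the same way by their median there.

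**Figure D1:**
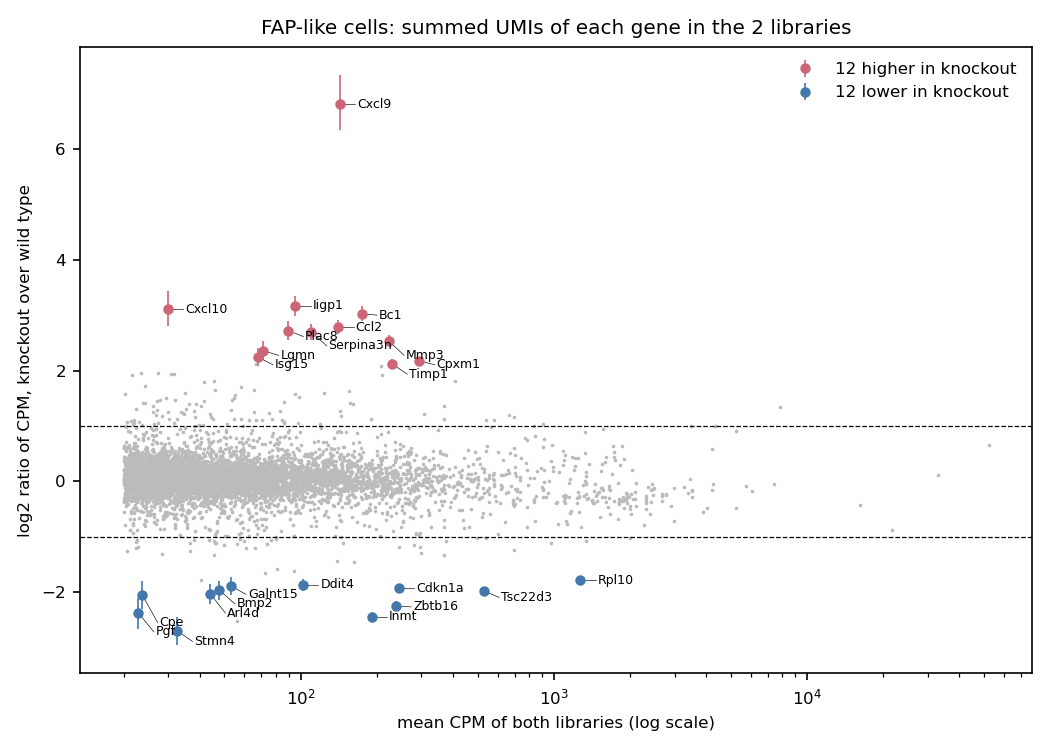
Each grey point is 1 of 5942 genes in FAP-like cells, by its mean CPM in the 2 libraries (log axis) and its log2 ratio of CPM, knockout over wild type. Coloured points with 95% counting intervals are the 12 higher and 12 lower genes chosen by rule, from Cxcl9 at 6.81 to Stmn4 at -2.70, and dashed lines mark 2-fold.

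Among the higher genes, Cxcl9, a chemokine for activated T cells (chromosome 5, 92321347 to 92328079), had 2.51 CPM in the wild type and 283 CPM in the knockout library, a log2 ratio of 6.81 (6.34 to 7.33). Its neighbour Cxcl10 had 6.21 and 53.6 CPM (log2 ratio 3.11, 2.80 to 3.44), and the monocyte chemokine Ccl2 (chromosome 11) had 35.7 and 246 CPM (2.78, 2.65 to 2.92). In the knockout library 63.3% of the Cxcl9 UMIs, 81.0% of the Cxcl10 UMIs and 64.1% of the Ccl2 UMIs came from the 138 cells of cluster 17, which Cxcl9 and Ccl2 help to define. Within shared clusters the median log2 ratio was 2.73 for Cxcl9 (5 clusters compared) and 2.44 for Cxcl10 (2 clusters compared). Shared cluster 4 went the other way for Cxcl10, with 33 wild type and 0 knockout UMIs (252 and 32 cells). The 0 kept it out of that median. For Ccl2 the median was 0.33, higher in 5 clusters and lower in 4. The interferon-induced GTPase Iigp1 had 19.1 and 172 CPM (3.17, 2.99 to 3.35) and the ubiquitin-like modifier Isg15 was 4.74-fold higher (2.24, 2.08 to 2.41), with medians within shared clusters of 1.48 and 1.60. The acute-phase protease inhibitor Serpina3n was 6.49-fold higher, and Plac8 6.60-fold (medians of 2.13 and 1.59 within shared clusters). The lysosomal protease Lgmn was 5.13-fold higher and went that way in 9 of 9 shared clusters. The matrix metalloproteinase Mmp3 had 65.5 CPM in the wild type and 380 CPM in the knockout library (2.54, 2.44 to 2.64), the metalloproteinase inhibitor Timp1 had 85.9 and 374 CPM (2.12, 2.03 to 2.21), and the carboxypeptidase-like gene Cpxm1 had 107 and 483 CPM (2.17, 2.10 to 2.25). Within shared clusters the medians were 0.58 for Mmp3, which is under 1.5-fold, 1.51 for Timp1 and 0.95 for Cpxm1. The small RNA Bc1, which is uncertain because it shares sequence with a transcript of Lrrc17, was 8.16-fold higher.

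Among the lower genes, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, had 845 CPM in the wild type and 215 CPM in the knockout library (log2 ratio -1.98, -2.03 to -1.93). The transcription factor Zbtb16 had 393 and 82.7 CPM (-2.25, -2.33 to -2.17), and the stress-responsive mTORC1 inhibitor Ddit4 had 161 and 44.0 CPM (-1.87, -1.99 to -1.75). The cell cycle inhibitor Cdkn1a was 3.80-fold lower (-1.93, -2.00 to -1.85). All 4 of these were lower in each of the 9 shared clusters, with medians there of -1.38 for Tsc22d3, -1.54 for Zbtb16, -1.59 for Ddit4 and -0.80 for Cdkn1a. The methyltransferase Inmt was 5.46-fold lower, Stmn4 had 56.4 and 8.67 CPM, and the vascular growth factor Pgf was 5.20-fold lower. Bmp2 (-1.96), Galnt15 (-1.89) and Arl4d (-2.03) were also lower. Within shared clusters the medians were -2.19 for Inmt, -1.38 for Stmn4, -0.90 for Pgf, -0.74 for Bmp2, -1.09 for Galnt15 and -1.28 for Arl4d. Cpe had a ratio of -2.05 but a median of -0.10 within shared clusters. Rpl10 had 1977 and 572 CPM (-1.79, -1.82 to -1.76). It is uncertain, because its close copy Rpl10-ps3 went the other way, with 554 CPM in the wild type and 841 CPM in the knockout library.

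Genes of the interferon response were higher as a group: 14 of 18 measured members were at least 1.5-fold higher and none was 1.5-fold lower. Their median log2 ratio was 1.09, at percentile 100 of the matched random lists, and the median over shared clusters was 0.72, above 0 in 9 of 9. Ifit3 was 3.02-fold, Oasl2 2.73-fold and Gbp3 2.86-fold higher, of which Ifit3 and Gbp3 have close copies; within shared clusters the medians were 0.33, 0.95 and 0.87. The class I MHC list had 7 of 11 members higher, a median of 0.89 (percentile 100) and a median over shared clusters of 0.36. B2m, the light chain of class I, had 403 and 930 CPM (1.21, 1.16 to 1.25), with a higher level in 9 of 9 clusters. H2-K1 was 2.16-fold, H2-D1 1.99-fold and H2-Q7 18.2-fold higher, but these belong to a family of near-identical genes that the counting may divide differently. Within shared clusters the medians of H2-K1 and H2-D1 were 0.27 and 0.36. The log2 ratio of H2-Q7, 4.18, was 3.26 with no cell filter, 2.21 with the stricter filter and 1.79 over all filtered cells. Class II MHC transcripts summed to 5.86 CPM in the wild type and 13.5 CPM in the knockout library.

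Chemokines and cytokines were split, with 6 of 14 members at least 1.5-fold higher, 2 lower and a median of 0.50 (percentile 100; 0.27 over shared clusters). Ccl7 was 4.36-fold higher, with a median of 0.59 within shared clusters, higher in 5 and lower in 4. Il33 had 110 and 146 CPM (0.40, 0.31 to 0.50), and Il6 had 8.03 and 10.5 CPM (0.39, 0.05 to 0.73). Of the complement genes, 4 of 10 were higher and 1 lower, with a median of 0.53 (percentile 99.98; 0.44 over shared clusters, above 0 in 9 of 9). Factor B, Cfb, was 4.22-fold, C4b 3.01-fold and C2 2.18-fold higher; Cfb and C2 are uncertain because both overlap the annotated gene Gm20547. Clu was 2.10-fold lower, but 0.67 higher on the log2 scale where each library was clustered alone. The NF-kB list had 1 member higher and 5 lower of 16, with a median of 0.03 at percentile 39.6 (0.23 over shared clusters). Its adhesion molecule Vcam1 was 2.76-fold higher in the knockout library and the inhibitor Nfkbia was 2.27-fold lower.

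The matrix lists had medians above 0, larger over the whole class than within shared clusters, and in each at least as many members lay within 1.5-fold as past it. The collagen list had 6 of 14 members at least 1.5-fold higher and none lower, with a median of 0.56 at percentile 100 and a median of 0.27 over shared clusters. Col3a1 had 4436 CPM in the wild type and 11197 CPM in the knockout library (1.34, 1.32 to 1.35), Col1a1 had 2330 and 4634 CPM (0.99, 0.97 to 1.01) and Col1a2 had 2909 and 5801 CPM (1.00, 0.98 to 1.01). Within shared clusters their medians were 0.49, 0.35 and 0.44, each under 1.5-fold. In the knockout library 57.7% of the Col3a1 UMIs came from cluster 1, which Col3a1 helps to define. Collagen maturation genes had a median of 0.35 (percentile 99.9; 1 of 13 higher, Lox at 1.65-fold), basement membrane genes 0.33 (percentile 99.5; 2 of 10 higher, among them Nid2 at 1.96-fold) and matrix glycoproteins and proteoglycans 0.16 (percentile 99.2; 8 of 23 higher, 1 lower). Their medians over shared clusters were 0.14, 0.10 and 0.14. Postn was 1.98-fold, Fn1 1.93-fold and Sparc 1.88-fold higher, while decorin, Dcn, had 18585 and 13856 CPM (-0.42, -0.43 to -0.42). Within shared clusters the medians were 1.02 for Postn and 1.01 for Fn1, but 0.25 for Sparc, which is under 1.5-fold. Matrix proteases and inhibitors had 8 of 18 members higher and 1 lower, with a median of 0.44 (percentile 100; 0.17 over shared clusters, above 0 in 9 of 9). Mmp14, the membrane-bound collagenase, was 1.96-fold higher and Adamts15 2.37-fold.

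TGF-beta signalling genes had a median slightly below 0. Of their 15 measured members 1 was at least 1.5-fold higher and 2 were lower, with a median of -0.14 (percentile 1.46) and a median of 0.05 over shared clusters. Tgfb1 had 31.4 and 25.2 CPM (-0.32, -0.51 to -0.13), Tgfbi was 1.77-fold and Ltbp4 1.57-fold lower, and Acta2 was 3.10-fold higher at 5.17 and 16.0 CPM. Within shared clusters the medians were -0.20 for Tgfbi and -0.15 for Ltbp4, each under 1.5-fold. With no cell filter the log2 ratio of Acta2 fell from 1.63 to 0.29, under 1.5-fold. Wnt and Hedgehog genes had a median of 0.25 (percentile 97.2; 0.44 over shared clusters, above 0 in 9 of 9), with the secreted Wnt modulators Sfrp1 and Sfrp2 3.78-fold and 2.71-fold higher.

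**Figure D2:**
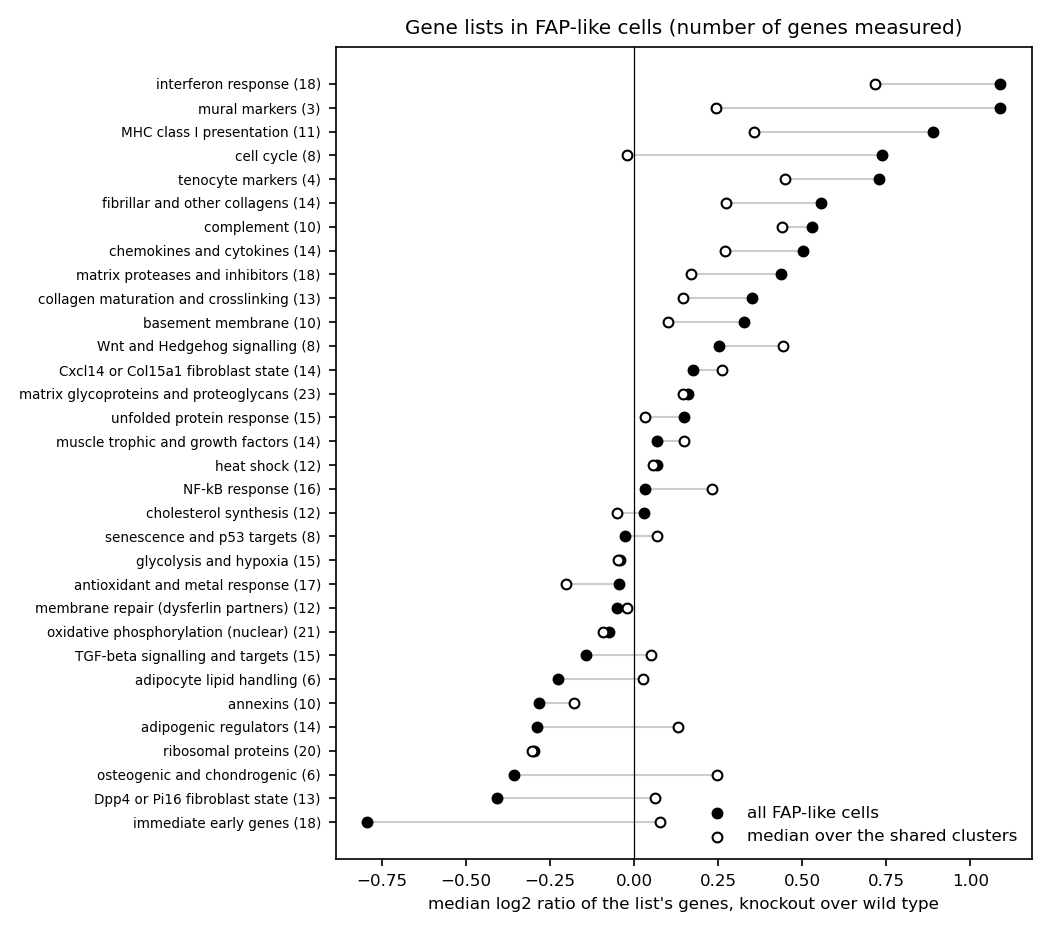
Median log2 ratio of CPM, knockout over wild type, for each list with at least 3 measured members; the number of members is in brackets. Filled points are sums over all FAP-like cells and open points are medians over the 9 shared clusters; the interferon list is at 1.09 and 0.72, and the immediate early genes are at -0.79 and 0.08.

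As a list, immediate early genes were lower over the class but not within shared clusters. In all FAP-like cells 14 of 18 members were at least 1.5-fold lower and 1 was higher, with a median of -0.79 at percentile 0 of the random lists. Over shared clusters the median was 0.08, above 0 in 5 and below 0 in 4, and cluster 4, which these genes define, was mostly wild type. Ier2 was 2.51-fold, Klf2 2.45-fold, Btg2 2.22-fold and Jund 2.17-fold lower, and Jund alone of these was lower in 9 of 9 clusters. These 4 members, picked by size, had medians below 0 within shared clusters: -0.51 for Ier2, -0.55 for Klf2, -0.44 for Btg2 and -0.71 for Jund. The heat shock list had 2 of 12 members lower, Hspb1 and Hspa1b at 1.77-fold and 1.51-fold, and a median of 0.07 (percentile 78.4). The unfolded protein response list had no member past 1.5-fold and a median of 0.15 (percentile 94.0). Over shared clusters the medians were 0.05 and 0.03.

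Adipogenic regulators had a median of -0.29 over the class (percentile 0.05), with 2 of 14 members at least 1.5-fold lower, 1 higher and 11 within 1.5-fold. Cebpd was 2.10-fold and Klf15 2.43-fold lower, both in 9 of 9 shared clusters, while Cebpa was 1.60-fold higher. The median over shared clusters was 0.13, above 0 in 6 of 9. The master regulator Pparg had 3.07 and 4.93 CPM (0.68, 0.15 to 1.23). The adipocyte hormone Adipoq had 0 UMIs in both libraries, which allows up to 0.209 CPM in the wild type and 0.161 CPM in the knockout FAP-like cells. Adipocyte lipid genes had a median of -0.23 (percentile 4.00; 0.03 over shared clusters; 2 of 6 lower), with Apoe 1.52-fold lower and Lpl 1.28-fold higher. Osteogenic and chondrogenic genes had a median of -0.36 (percentile 0.56) but 0.25 over shared clusters and 0.85 without clusters 0 and 6. Of 6 members 2 were higher, Runx2 2.15-fold and Mgp 1.51-fold, and 3 lower, Bmp2 3.90-fold, Alpl 1.94-fold and Comp 1.59-fold.

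Annexins had a median of -0.28 (percentile 0.89; -0.18 over shared clusters, below 0 in 8 of 9), with Anxa11 2.16-fold and Anxa3 1.54-fold lower. Over the cells of the shared clusters alone the log2 ratio of Anxa3 was 0.014. Anxa1 had 533 and 441 CPM (-0.27, -0.32 to -0.23) and Anxa2 had 952 and 863 CPM (-0.14, -0.17 to -0.11). Of 12 membrane repair genes none passed 1.5-fold and the median was -0.05 (percentile 17.3; -0.02 over shared clusters). Myof, a dysferlin homologue, had 80.6 and 97.0 CPM (0.27, 0.16 to 0.38).

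Among muscle trophic factors 2 of 14 were higher and 4 lower, with a median of 0.07 (percentile 73.4; 0.15 over shared clusters). Hgf, a satellite cell activator, was 3.54-fold higher (1.82, 1.47 to 2.19) and was higher in the 8 shared clusters where it was measured. Igfbp6 was 2.04-fold and Gdf10 1.85-fold lower. Igf1 had 500.4 and 560 CPM (0.16, 0.12 to 0.21), and the myostatin antagonist Fst had 216 and 162 CPM (-0.41, -0.48 to -0.34).

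Ribosomal protein genes had a median of -0.30 (percentile 1.11), and the median was below 0 in 9 of 9 shared clusters. They made up 14.6% of the wild type and 11.9% of the knockout FAP-like UMIs. Nuclear genes of oxidative phosphorylation had a median of -0.08 (percentile 13.5), cholesterol synthesis 0.03 (percentile 36.2), glycolysis and hypoxia -0.04 (percentile 14.9), the antioxidant and metal response -0.04 (percentile 27.7), and senescence and p53 targets -0.03 (percentile 21.2). Their medians over shared clusters were -0.09, -0.05, -0.05, -0.20 and 0.07. No member of the oxidative phosphorylation or cholesterol lists passed 1.5-fold. Of the glycolysis and hypoxia genes 2 of 15 were higher and 3 lower, of the antioxidant genes 1 of 17 higher and 3 lower, and of the p53 targets 1 of 8 lower (Cdkn1a). Hif1a, which overlaps the annotated gene Gm49321, was 2.97-fold higher over the class and higher in 9 of 9 clusters, Ldha 1.58-fold higher and Gstm1, which has a close copy, 1.93-fold lower; Eno1 was 1.95-fold lower but shares sequence with Eno1b. The cell cycle list had 4 of 8 members higher and a median of 0.74 (percentile 100), and -0.02 over shared clusters. Top2a had 6 wild type and 488 knockout UMIs, of which 96.9% came from 19 knockout cells in cluster s9, which cell cycle genes define.

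FAP sub-state genes were compared at equal depth. After thinning, Cxcl14 had a UMI in 42.9% of wild type cells (40.4 to 45.5) and 66.0% of knockout cells (63.5 to 68.5). Its background in endothelial-like cells was 10.3% (2.19 to 27.4; 29 cells). Without thinning the Cxcl14 shares were 50.9% and 77.1%. Over the cells of the shared clusters alone its log2 ratio of CPM was -0.049, against 0.63 over the class and a median of 0.85 within those clusters. Dpp4 was found in 20.5% (18.4 to 22.6) and 14.3% (12.5 to 16.3) of thinned cells, and in 0 of the 29 endothelial-like cells (interval up to 11.9%). Without thinning its shares were 36.1% and 36.0%. With cells thinned to 1400 UMIs the Dpp4 shares were 11.4% (9.87 to 13.1) and 10.2% (8.67 to 11.9), whose intervals overlap. Pi16 was found in 48.5% and 45.3% of thinned cells, whose intervals overlap, and in 61.5% and 67.0% of cells without thinning; its background was 6.90%. Cxcl9 was found in 0.551% of wild type cells (0.238 to 1.08) and in 12.1% of knockout cells (10.4 to 13.9). Its share in endothelial-like cells was 6.90% (2 of 29 cells, 0.846 to 22.8). That interval overlaps both others, so this background sets neither library's share apart. Unthinned shares were 1.37% and 22.2%. The endothelial-like cells were shallower, with a median of 3276.5 UMIs before thinning. The gate gene Pdgfra was found in 69.7% and 70.6% of thinned cells and in 89.8% and 92.3% of unthinned cells, and its CPM values, 477 and 484, differed by 0.02 on the log2 scale (-0.03 to 0.06). The list of the Dpp4 or Pi16 state had a median of -0.41 (percentile 0.01) but 0.06 over shared clusters, and that of the Cxcl14 or Col15a1 state had 0.17 (percentile 97.3) and 0.26. Of their members, 1 of 13 and 2 of 14 were at least 1.5-fold higher, and 5 and 2 lower. Cd34 had 910 and 661 CPM (-0.46), and Ly6a, which encodes SCA-1 and has a close copy, had 1404 and 1795 CPM (0.35).

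Among marker lists of other cell types, tenocyte markers had the highest sums in the FAP-like cells, 680 CPM in the wild type and 1067 CPM in the knockout library, of which Thbs4 gave 583 and 982 CPM. Macrophage markers summed to 5.17 CPM in the wild type and 7.66 CPM in the knockout library (log2 ratio 0.57, 0.15 to 0.99), endothelial markers to 11.9 and 9.42 CPM (-0.33, -0.65 to -0.02), satellite cell markers to 24.4 and 14.2 CPM (-0.78, -1.02 to -0.55) and myofibre transcripts to 42.0 and 39.8 CPM (-0.08, -0.24 to 0.08). Glial markers summed to 36.1 and 25.3 CPM (-0.51), and haemoglobin to 7.82 and 5.94 CPM (-0.40). Mast cell markers summed to 2.09 CPM in the wild type and 10.7 CPM in the knockout library (2.35, 1.79 to 2.95), and neutrophil markers to 1 and 16 UMIs (3.62, 0.93 to 9.01). The macrophage, endothelial, satellite cell, myofibre, glial, haemoglobin and class II MHC lists had fewer than 3 measured members, so no median was taken. Mural markers, with 3 measured members, had a median of 1.09 (percentile 99.9; 0.24 over shared clusters), led by Acta2 and Tagln (2.12-fold) at low CPM. Tenocyte markers had a median of 0.73 with 4 measured members (percentile 99.9; 0.45 over shared clusters), with Thbs4 1.68-fold higher and Comp 1.59-fold lower. Over the cells of the shared clusters alone the list was at -0.48 and Thbs4 at -0.59, and Comp was at 0.58 with each library clustered alone. The naming rule itself bears on the tenocyte list. It left out cluster s2 (43 wild type and 21 knockout cells), which carried the tenocyte markers Tnmd and Fmod. Over all filtered cells the log2 ratio of Fmod was -0.20, against 0.71 in the FAP-like cells.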

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

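With 1 library per group, no sample of a group can be set against the others, so the result below is a group of cells outside the comparisons of the report. The tests of immune RNA, of heat shock genes and of the 2 measured Rpl10 copies taken alone below were chosen after the result was seen; the other tests were fixed before their values were looked at, on patterns already seen.

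Cluster s10, unnamed, held 43 of the 1578 knockout cells (2.72%, 1.98 to 3.65) and 0 of the 1793 wild type cells, which allows up to 0.206%. Its cells carried FAP markers (Pdgfra UMIs in 88.4% of them, Col3a1 in 100%) together with transcripts of unrelated types: Hbb-bs at 408 CPM against 2.57 CPM in the knockout FAP-like cells, the mast cell protease Mcpt4 at 142 against 5.51 CPM, and Igkc at 54.4 against 2.57 CPM. Their mitochondrial share was 8.68% and their median depth 12574 UMIs. Cluster s0, which is also unnamed and has haemoglobin genes among its leading genes, was mostly wild type, with 45 wild type and 4 knockout cells.

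The first pattern is the higher level of interferon-induced, class I MHC and chemokine genes in the knockout FAP-like cells. The tables argue against RNA of immune cells: 5 leukocyte transcripts allow at most 0.139% of it in these cells, by the profile of the 18 immune cells in the data, while the 27 genes that were at least 1.5-fold higher would need a median of 82.7% and at least 7.27% (100% where immune cells were no higher). Mast cells were not among those 18 cells, and their markers were at 2.09 CPM in the wild type and 10.7 CPM in the knockout FAP-like cells. The interferon median was 1.19 with every cell thinned to the same number of UMIs and 1.09 without. Thinning leaves the expected CPM of a cell as it was. It therefore shows only that the greater weight of deep cells was not the source, and decides nothing further about depth. Clusters found almost only in the knockout library were not the whole source for the interferon list, whose median over shared clusters was still 0.72. The class I MHC list went from 0.89 over the class to 0.36 over shared clusters. The chemokine and cytokine list went from 0.50 to 0.27, above 0 in 6 of 9. Dysferlin loss, strain, housing and the separate preparation of the libraries stay open and with 1 library per group none of them was tested.

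The second pattern is the lower level of immediate early genes and of genes known to be induced by glucocorticoids, such as Tsc22d3, Zbtb16 and Ddit4. Within shared clusters the list of immediate early genes had a median of 0.075, above 0 in 5 of 9. Tsc22d3, Zbtb16 and Ddit4, which were picked by size, were lower in 9 of 9. The immediate early genes picked by size also had medians below 0 there: Jund -0.71, Klf2 -0.55, Ier2 -0.51 and Btg2 -0.44. A list set against genes picked by size therefore does not show that the 2 parts of the pattern differ. Different times of day at collection stay open. Of 5 clock output genes, 3 (Dbp, Tef and Per3) lay within 1.5-fold, which had been set in advance as evidence against. That bound took the 5 genes to move together, but Nr1d1 was lower at -1.20 (-1.33 to -1.07) in 9 of 9 shared clusters and Nr1d2 1.58-fold lower, while Arntl went the other way at 0.31 (0.13 to 0.49) in 8 of 9. Other rows do not line up with these: Npas2, expected to go with Arntl, was at 0.014 (-0.245 to 0.275), and Tef (0.28, 0.08 to 0.47) and Per3 (0.31, 0.11 to 0.53) were higher, against Nr1d1. The clock genes therefore decide neither way. Lower glucocorticoid exposure remains a candidate explanation: among further targets the 7 measured had a median log2 ratio of -0.34, at percentile 0.31 of matched random lists, with 2 at least 1.5-fold lower and none higher, and a median of -0.38 over shared clusters. Angptl4 was at 0.14 over the class but lower in 9 of 9 shared clusters, and the rest were below 0 over the class. Per1, which is also a clock gene, was at -0.26 over the class but higher in 7 of 9 shared clusters. Handling stress at isolation stays open, since the heat shock median of 0.067 rested on members that went both ways, 2 of them lower. With 1 library per group, the handling of the animals and dysferlin loss were not tested as sources.

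The third pattern is the 3.46-fold lower Rpl10 beside a higher pseudogene copy. A move of reads between the 2 measured copies would keep their sum, but the summed CPM was 2531 in the wild type and 1413 in the knockout library, a log2 ratio of -0.84 (-0.86 to -0.82). Transfer between these 2 copies was therefore not the whole source. A sum at least 1.5-fold lower had been set in advance as evidence against transfer between all copies, and this sum met it. That bound took every copy to be counted. The annotation holds 14 such genes, Rpl10 among them, and the files hold only these 2, so transfer to the other 12 stays open. A sequence variant that makes reads align equally well to several copies, and so drops them from the counts, was not tested.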

How the results depend on the processing

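The 3 alternatives that leave out clusters 0 and 6, that keep the shared clusters alone, and that take the median over shared clusters were chosen after seeing the data; the others were planned. No paired analysis was possible because no file maps cells to the 4 samples of a group, and for the same reason leaving out replicates and comparing DESeq2 with edgeR as tests were not run. Of 104 named genes at least 1.5-fold apart, 104 kept their direction at resolution 1.2, with equal weight per cell, and in cells with a Pdgfra UMI. After thinning, 103 of the 103 measured did so. This is a weak check, because most of these genes were picked by size in the same counts. Cells with a Pdgfra UMI were also 89.8% of the wild type and 92.3% of the knockout FAP-like cells. TMM scaling, size factors and a total without mitochondrial and ribosomal protein genes move every gene alike, by 0.03 to 0.05 on the log2 scale, so they are no check of direction. The direction together with at least 1.5-fold was kept by 93 of 103 after thinning, by 92 of 104 with no cell filter, by 91 of 104 with each library clustered alone, by 66 of 104 over the cells of the shared clusters and by 57 of 102 as medians over shared clusters. The causes of the shifts below were not tested, except that lower or higher expression minimums test more or fewer genes. Depth limits Dysf, genes below about 10 CPM and the rare classes.

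The FAP-like share was 82.9% of wild type and 81.1% of knockout cells with no cell filter, 97.7% and 99.6% with at least 1000 genes and at most 5% mitochondrial UMIs, 94.5% and 96.1% at resolution 0.4, 93.8% and 95.4% with 15 components, 78.2% and 94.7% with each library clustered alone, and 72.3% and 84.6% without clusters 0 and 6. It was 94.0% of wild type cells with doublets kept. The numbers of genes at least 2-fold higher and lower were 245 and 131 at a mean CPM of at least 5, 55 and 37 at 50, 148 and 71 without clusters 0 and 6, and 53 and 31 over shared clusters alone, against 107 and 58.

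The log2 ratio of Fmod turned to -0.61 with no filter, -0.33 with the stricter filter, -0.39 with doublets kept, -0.33 at resolution 0.4 and -0.20 over all filtered cells. The cell cycle list turned to -0.089 with no filter. With each library clustered alone, Clu was at 0.67 and Comp at 0.58. Without thinning, the knockout share of cells was 2.30 points higher for Cd55 and 0.55 points higher for Sema3c. Without clusters 0 and 6, Comp and the osteogenic list were each at 0.85.

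Over shared clusters alone, Anxa3 was at 0.014, Efhd1 at 0.037, Cxcl14 at -0.049 and Thbs4 at -0.59, and the lists of TGF-beta at 0.022, cell cycle at -0.071, the Dpp4 or Pi16 state at 0.28 and tenocytes at -0.48. As medians over shared clusters, Ier3 was at 0.60, Nfkbiz at 0.44, Ndrg1 at 0.19, Mt2 at -0.0035, Penk at 0.23 and S100b at 0.063. The lists so taken were TGF-beta at 0.050, adipogenic regulators at 0.13, immediate early genes at 0.075, cell cycle at -0.022, the Dpp4 or Pi16 state at 0.062 and osteogenic genes at 0.25.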

Other observations

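All tests in this part were fixed before their values were looked at, but after the deposited data had been examined for other results.

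Besides the lists of the report, dysferlin transcripts stood out in the few endothelial-like cells: after thinning, Dysf had a UMI in 7 of 29 of them (24.1%, 10.3 to 43.5), against 0.138% of wild type and 0.145% of knockout FAP-like cells. These 29 cells pool both libraries and clusters s4 and s5. Counted over the filtered cells outside the FAP-like class, Dysf had 15 wild type UMIs (11.3 CPM) and 2 knockout UMIs (1.68 CPM), a ratio of 0.148 (0.0165 to 0.638). The wild type library held 40 endothelial-like cells and the knockout library 6, so this ratio also carries the difference in cell makeup. All 6 of these knockout cells were in cluster s5, which has lymphatic markers among its leading genes, and cluster s4 held 28 wild type and 0 knockout cells.

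Chemokine and interferon-induced transcripts in the knockout library were unevenly spread over the FAP-like cells. Cluster 17, with 9.38% of its FAP-like cells, gave 57.5% of the Ccl7 UMIs, 46.5% of the Isg15 UMIs and 43.9% of the Iigp1 UMIs, while B2m came to 13.6% from this cluster and to 49.2% from cluster 1, which holds 38.9% of the cells. Of the H2-Q7 UMIs, 55.2% came from cluster 1 and 23.8% from cluster 17. Shares of UMIs also follow depth. Knockout cells had a median of 13955.5 UMIs in cluster 1 and 12760.5 in cluster 17, against 12164 over all FAP-like cells of that library. Ccl7, Isg15 and Iigp1 are among the 10 leading genes of cluster 17, so their concentration there follows in part from the clustering.

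If the Dysf allele of the knockout animals came from the A/J strain, it may carry a segment of that strain's chromosome 6. A segment that changed the expression of many of its genes would make genes near Dysf differ more than others. The 57 measured genes within 10 Mb of Dysf had a median absolute log2 ratio of 0.15, at percentile 27.4 of matched random lists, and 1 of them (Cyp26b1, 2.39-fold lower, picked out after its value was seen) was past 2-fold. Cyp26b1, which starts at 84571414, is the next measured gene after Dysf, which ends at 84211060. The same was asked of the MHC region on chromosome 17, where Cfb, C4b, C2 and the H2 genes lie. There, 42 measured genes outside the interferon, MHC and complement lists had a median absolute log2 ratio of 0.19, at percentile 53.3, and 0 were past 2-fold. This percentile met the bound that had been set in advance as evidence against another haplotype of the region. The bound does not settle whether the region differs, because 12 genes of the lists lie in it and were left out, 5 of them past 2-fold. The genes near Dysf did not differ more than others as a set, which bears on expression and not on sequence. A median over the set cannot show a change in a few genes, so an effect of a segment on single genes such as Cyp26b1 was not tested.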
